A study of Homo sapiens with 24 samples.

How the data were processed

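Enhanced crosslinking and immunoprecipitation followed by sequencing (eCLIP) was used to map the RNA bound by individual proteins in 293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels' protocols, plated cells were irradiated with ultraviolet light at 254 nm and 400 mJ/cm2, lysates were briefly digested with RNase I, and protein-RNA complexes were precipitated with an antibody against RBFOX2, an antibody against SLBP or an isotype control IgG. An RNA adapter was ligated on the beads, complexes were run on a protein gel, and membrane from the protein's size up to 75 kDa above it was excised. Reverse transcription was followed by ligation of a DNA adapter that carried a random-mer of 5 or 10 bases. Each of the 7 immunoprecipitations with a peak list had an input sample of its own, and among these the RNase I amount was 40 U except in SLBP replicates 3 and 4, which received 5 U together with their inputs.

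The series lists 24 samples, of which 7 had peak lists and entered the comparisons: 2 RBFOX2, 4 SLBP and 1 IgG. The 7 input samples entered only through the authors' fold values, and the 10 RBFOX2 samples of an RNase I series with 8 amounts were not analysed here. Antibodies and replicate numbers were taken from the sample titles, and RNase I amounts from the sample labels. Nothing in the labels says that replicates came from separate cultures, so SDs and permutation p-values describe the spread between these libraries, which may be technical. Fisher's exact p-values rest on counts of peaks or regions and hold no spread between libraries.

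Each deposited peak list holds 1 interval per peak with its strand, a −log10 p-value and a log2 fold; the columns carry no header, and their units were read from the values and from the naming of the lists as input-normalized. The deposited log2 fold is the authors' value of immunoprecipitation over the paired input at that peak. The deposited −log10 p ran from 0 to a ceiling of 400, and every peak with a log2 fold under 0 had the value 0. A second pile-up lay at 15.66 and held 1684 and 1887 peaks in the RBFOX2 lists; what set it is not given in the sources used here. The p-value was therefore used as a filter and not to rank peaks. The build was hg19, and cutadapt, STAR, GATK, Picard and SAMtools were used, per the submitters' processing notes, without versions; the peak caller and the details of the normalization are not given in the sources used here. Each library had its own list with its own intervals, so peaks were treated as called per library. No peaks of 1 strand overlapped within a list, but many touched end to end, so 1 binding site could be split into several peaks. The lists give no read counts, so the sequencing depth behind a fold is unknown and no interval for a single fold can be given. Exact binomial 95% intervals on shares of peaks cover counting error only.

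A peak was called enriched when the authors' −log10 p was at least 5 and their log2 fold at least 3, which is 8-fold over input. These limits were fixed before the data were examined, as were the tests and alternatives other than those said to have been added later. Enriched peaks were counted in each library, and enriched peaks of different libraries were matched when they shared at least 1 nt on the same strand. Whether enriched peaks coincided was tested with a two-sided Fisher's exact test over the peaks of 1 library that touched any peak of the other; peaks are not independent replicates, and this test compares libraries, not conditions. Library-level values were compared with two-sided exact permutation tests. The smallest p that these can give is 0.133 for 2 RBFOX2 against 4 SLBP libraries and 0.333 for 2 against 2, so no such comparison could pass 0.05. Fold values were used to filter and rank peaks within a list. Folds from different lists mostly stand side by side without a test; medians of them per library, such as those of mitochondrial peaks, were compared only by the permutation tests, whose values rest on scalings that are not known to match.

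A reproducible region was a stretch of nucleotides covered by enriched peaks in all libraries of an antibody. Regions within 1 kb of each other on a strand were joined into loci, a step chosen after the lists were seen, because the peaks carry no gene names. No hg19 genome or annotation was used here, and the gene table at hand is on GRCh38.p14, so loci are given by hg19 coordinates (counted from 1) and strand without gene names. The planned analyses of the RBFOX2 motif, of hexamers, of exons and introns, of the histone stem-loop sequence and of gene lists could not be run, and the genes RBFOX2, SLBP and NDEL1 were not located. Replication-dependent histone genes were represented by 4 windows on hg19 fixed in advance from general knowledge of where these clusters lie and not checked against an hg19 annotation, and every histone share depends on them: HIST1, chromosome 6 from 26 to 28 Mb; HIST2, 200 kb of chromosome 1; HIST3, 100 kb of chromosome 1; and HIST4, 20 kb of chromosome 12. The GRCh38.p14 table was used only to count histone gene names per chromosome. By the rule fixed in advance, the loci named are the 15 of each antibody with the highest log2 fold in their weakest library and the 5 enriched IgG peaks with the highest fold; other loci named are said to have been chosen after their values were seen. The rule would have left out pseudogenes and abundant non-coding RNAs, which could not be recognised without an annotation.

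The overlap and intersection steps were tested on simulated data. Overlap calls on 1600 simulated intervals differed from brute force in 0 cases. In a list simulated from the 74902 peaks of RBFOX2 replicate 1, in which 70% of enriched peaks were shared by construction, 72.5% were found shared, and 8.75% when the partner peaks were drawn at random. Alternatives covered other thresholds, another overlap rule, strand, mitochondrial peaks, covered nucleotides, pairing by replicate number and leaving out each library. Merging touching peaks (for counts, widths and IgG), leaving out peaks at enriched IgG peaks and the thresholds applied to IgG were added after the data were seen, as were the tests by chromosome, of the 100 highest and lowest RBFOX2 regions and of enriched IgG peaks at RBFOX2 sites. The 100 highest and lowest regions were chosen before that result was seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.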

Results

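The data comprised 7 eCLIP peak lists from 293T cells. RBFOX2 is a splicing regulator whose RNA recognition motif binds (U)GCAUG elements, many of them in introns. SLBP, the stem-loop binding protein, binds the stem-loop at the 3' end of replication-dependent histone mRNAs. The design implies 4 comparisons: each antibody against its input and against the IgG control, replicates against each other, RBFOX2 against SLBP, and SLBP at 40 U against 5 U of RNase I. The RBFOX2 lists held 74902 and 97594 peaks, the IgG list 28361, and the SLBP lists 23034, 18349, 16974 and 10122 for replicates 1 to 4. All folds and p-values of single peaks are the authors' own, and the read depth behind them is unknown.

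RBFOX2 immunoprecipitation recovered many sites above input, with reproducible loci on every autosome and the X chromosome, and IgG recovered few that passed both limits. Enriched peaks numbered 5954 in RBFOX2 replicate 1 and 7480 in replicate 2, a mean of 6717 ± 1079 (SD, n = 2), or 7.81% ± 0.20 (SD, n = 2) of all peaks. The single IgG library had 51 enriched peaks, 0.180% of its peaks (exact 95% interval 0.134 to 0.236). RBFOX2 peaks also lay below input often: 32.6% and 31.0% had a negative log2 fold in replicates 1 and 2, against 10.7% in IgG. With 1 IgG library the difference has no replicate check. On the fold limit alone, 8974 and 11300 RBFOX2 peaks and 1168 IgG peaks passed. Of these, 66.3%, 66.2% and 4.37% also passed the p-value limit. Much of the contrast thus rests on the p-value limit, at unknown read depth. The IgG count depended more on the limits: it was 135 with the looser p, 168 with the looser fold and 15 with the stricter limits, where RBFOX2 averaged 8538.5, 8545.5 and 2975.5. The median enriched RBFOX2 peak was 55 nt wide in replicate 1 and 51 nt in replicate 2.

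**Figure D1:**
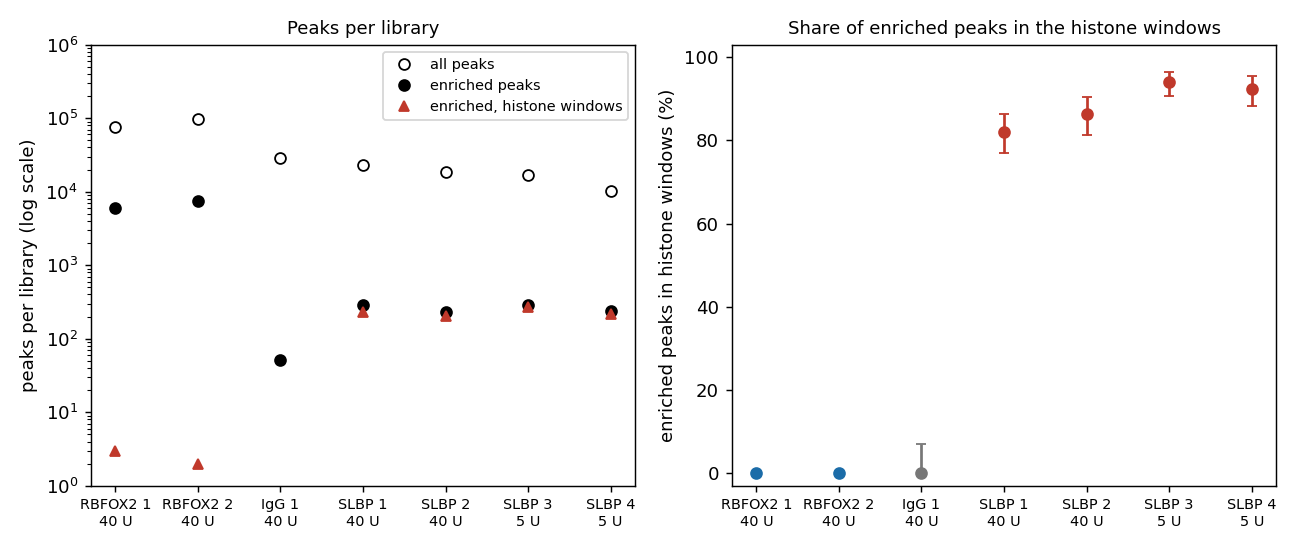
Left, number of peaks per library on a log scale, with all peaks as open circles, enriched peaks as filled circles and enriched peaks in the histone windows as triangles (0 in IgG, not drawn). Right, percent of enriched peaks in the histone windows per library with exact binomial 95% intervals; the 4 SLBP libraries lie between 82.0% and 94.1%, and the RBFOX2 libraries at 0.050% and 0.027%.

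The same RBFOX2 sites passed in both replicates more often than other sites did. Of the enriched peaks of replicate 1, 4089 (68.7%) overlapped an enriched peak of replicate 2, and 4544 (60.7%) did so in the other direction. Among replicate 1 peaks that touched any peak of replicate 2, 74.4% of the enriched ones and 5.79% of the others lay on an enriched peak of replicate 2 (odds ratio 47.2; Fisher's exact p too small to be represented). Across 42130 peaks of replicate 1 whose midpoint lay in a replicate 2 peak, log2 folds correlated with Pearson's r of 0.84 and Spearman's rho of 0.82; peaks are not independent replicates, and this describes the 2 lists.

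Nucleotides enriched in both RBFOX2 libraries formed 2618 regions (939 with the stricter limits) with a median width of 64 nt. The 2618 regions joined into 1585 loci. The loci split about evenly by strand, 52.7% of them on the plus strand, and 443 (27.9%) held more than 1 region. The most regions in a locus was 13, at chromosome 19 positions 10906918 to 10909005 on the plus strand, a locus chosen after its values were seen. Chromosomes 1, 19 and 17 held the most loci, with 146, 111 and 105. As a share of the peaks called on each chromosome, enrichment was highest on chromosome 22 in replicate 1 (13.4%, odds ratio 1.84, Benjamini-Hochberg adjusted Fisher's exact p = 4.25e-17) and was 12.3% there in replicate 2 (odds ratio 1.73, adjusted Fisher's exact p = 6.39e-18). In replicate 2 the share was highest on chromosome 21 (12.8%, odds ratio 1.78, adjusted Fisher's exact p = 5.67e-09), which had 11.3% in replicate 1. Chromosome 20 stood at 12.2% and 12.5% in replicates 1 and 2. Chromosome 12 had the lowest share of the autosomes in both, at 5.61% and 5.35%. Other chromosomes differed more between replicates 1 and 2. Chromosome 18 stood at 10.7% and 6.53% (adjusted Fisher's exact p = 0.00361 and 0.155), and chromosome 10 at 12.2% and 9.65%. Chromosome 19 went the other way, at 8.69% and 10.9% (adjusted Fisher's exact p = 0.0600 and 6.90e-23). Touching pieces of 1 site count separately in these tests, so their p-values overstate the evidence in sites. None of the 226 and 195 mitochondrial peaks of the RBFOX2 lists was enriched (0 in both libraries). Their median log2 folds were −1.06 and −1.43, and 86.3% and 97.9% of them lay below input, against 66.2% of the 157 mitochondrial IgG peaks.

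The 15 RBFOX2 loci with the highest fold in their weaker replicate had log2 folds of 7.60 to 8.89 in that replicate. The first lay on chromosome 2 at 240287226 to 240288011 on the minus strand, with log2 folds of 8.89 and 9.42 in replicates 1 and 2. The next were on chromosome 14 at 105812242 to 105814456 (plus strand, 11 regions, 8.93 and 8.76) and on chromosome 16 at 3104068 to 3104857 (minus strand, 9.16 and 8.72). Chromosome 5 at 139646449 to 139646781 (minus strand) reached 8.88 and 8.32, and chromosome 7 at 100172829 to 100173458 (minus strand) reached 8.30 and 9.14. Chromosome 13 at 111314398 to 111314830 (minus strand) had 8.06 and 8.13, and chromosome 1 at 3638958 to 3639860 (plus strand) had 9.12 and 8.05. The widest gaps between replicates were at chromosome 1, 227954808 to 227957039 (plus strand, 10.05 and 7.75), and at chromosome 6, 131200532 to 131201257 (minus strand, 9.55 and 7.61). The remaining 6 were on chromosome 17 at 80807526 to 80808682 (plus), chromosome 20 at 62298969 to 62299922 (plus), chromosome 18 at 11767149 to 11767802 (plus), chromosome 10 at 3127101 to 3127148 (plus), chromosome 10 at 3166697 to 3167381 (plus) and chromosome 16 at 87738667 to 87740913 (minus), with lower-replicate log2 folds of 7.60 to 7.85. In the IgG list, 14 of these 15 loci held a peak and 9 an enriched one. In each SLBP list 1 or 2 of them held a peak, and 0 of the 15 held an enriched SLBP peak in any of the 4 libraries.

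SLBP immunoprecipitation recovered fewer enriched peaks, and most of them lay in the replication-dependent histone gene windows. Enriched peaks numbered 284, 233, 289 and 236 in replicates 1 to 4, a mean of 260.5 ± 30.1 (SD, n = 4). Of these, 233, 201, 272 and 218 lay in the 4 histone windows, 88.7% ± 5.6 (SD, n = 4) of the enriched peaks. The shares were 82.0%, 86.3%, 94.1% and 92.4%. With touching peaks merged, the enriched SLBP peaks made 126 sites on average, with a mean share of 87.0% in the windows. In the RBFOX2 libraries 3 of 5954 (0.050%) and 2 of 7480 (0.027%) enriched peaks lay there. In IgG the count was 0 of 51, which allows a share of up to 5.88% taken as 3 counts of the total, or up to 6.98% by the exact 95% interval. The windows were not checked against an annotation. Within the SLBP lists, peaks that were not enriched lay in the windows in 0.145% to 0.234% of cases; the odds ratio of enriched against non-enriched peaks was between 3145 and 6829, with Fisher's exact p too small to be represented. Against the peaks below input alone, the largest Fisher's exact p of the 4 libraries was 2.55e-239. All 4 SLBP libraries had higher shares than both RBFOX2 libraries, with the smallest p that the exact permutation test can give (p = 0.133, two-sided, n = 4 and 2).

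Most SLBP peaks in the windows were enriched. Of the 266, 230, 311 and 237 peaks of replicates 1 to 4 there, 87.6%, 87.4%, 87.5% and 92.0% passed, against 1.56% and 0.870% of the 192 and 230 RBFOX2 peaks and 0 of 83 IgG peaks. The median log2 fold of all window peaks was 5.67, 7.12, 5.07 and 6.49 in the SLBP libraries. It was −0.56 and −1.10 in the RBFOX2 libraries and 0.57 in IgG. The HIST1 window, which spans the main histone cluster of chromosome 6, held most of the enriched peaks in each SLBP library. The HIST2 window held 28, 29, 31 and 25 of them, the HIST3 window 3, 2, 6 and 5 and the HIST4 window 5, 7, 6 and 6.

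Within HIST1 the SLBP signal fell into 3 blocks separated by long stretches without reproducible sites. The blocks are defined by reproducible loci less than 100 kb apart, a description made after the data were seen. The first, at 26021078 to 26285699, held 20 loci, the second, at 27100105 to 27115303, held 4, and the third, at 27775260 to 27861663, held 9. Together the blocks held 194, 156, 222 and 179 enriched peaks in SLBP replicates 1 to 4, and 3, 7, 7 and 3 lay elsewhere in the HIST1 window. Inside the blocks the RBFOX2 and IgG lists had 0 enriched peaks. The RBFOX2 lists held 69 and 90 peaks there with median log2 folds of −0.92 and −1.50, and 87.0% and 97.8% of them lay below input. The 45 IgG peaks had a median log2 fold of 0.27, and 28.9% lay below input. The enriched RBFOX2 peaks of the windows all lay between the blocks, on the plus strand of chromosome 6 at 26597481 to 26597699 in replicate 1 (3 peaks, highest log2 fold 4.01) and at 26597480 to 26597606 in replicate 2 (2 peaks, highest 4.46); this position was chosen after its values were seen.

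**Figure D2:**
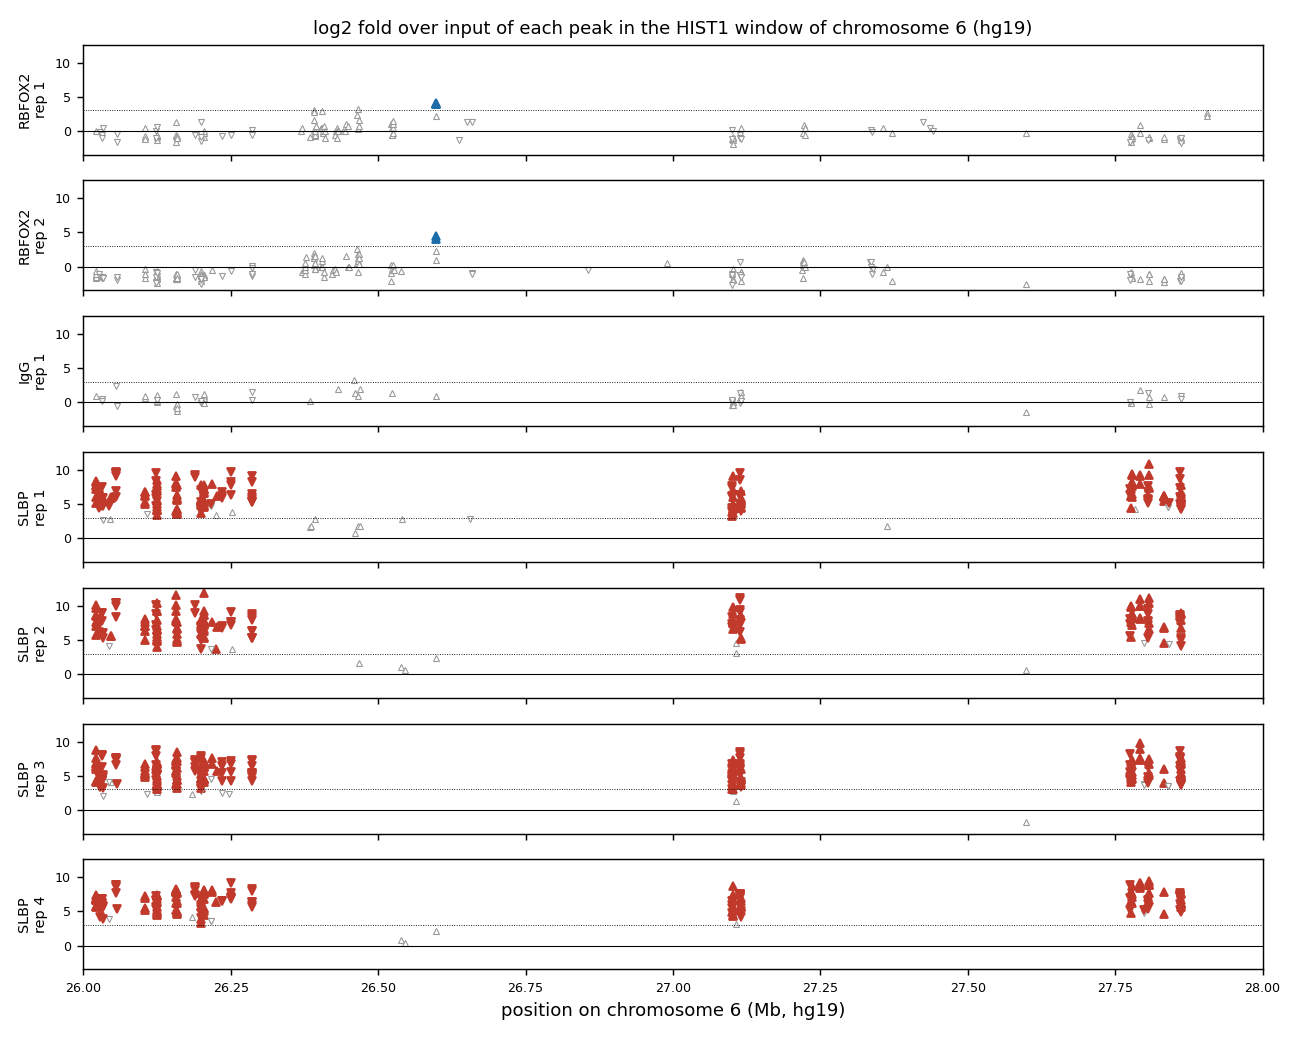
Authors' log2 fold over input (vertical axis) of each peak along the HIST1 window of chromosome 6 (horizontal axis, hg19 position in Mb), by library. Triangles point up for the plus strand and down for the minus strand, filled symbols are enriched peaks, open grey symbols are not, and the dotted line marks a log2 fold of 3; SLBP peaks stand in 3 blocks where the RBFOX2 lists had 0 enriched peaks.

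Nucleotides enriched in all 4 SLBP libraries formed 90 regions in 44 loci, of which 42 (95.5%) lay in the histone windows. HIST1 held 33 of the loci, HIST2 6, HIST3 2 and HIST4 1, and 21 of the 42 lay on each strand. For scale, the GRCh38.p14 gene table names 70 protein-coding replication-dependent histone genes, 55 on chromosome 6, 14 on chromosome 1 and 1 on chromosome 12; loci were not matched to genes. None of the 42 loci held an enriched IgG or RBFOX2 peak (0 in each of the 3 libraries). The RBFOX2 lists had 56 and 69 peaks at these loci, with median log2 folds of −0.99 and −1.52.

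The 15 SLBP loci with the highest fold in their weakest library all lay in the histone windows, 13 of them in HIST1. The first was chromosome 6 at 27792177 to 27792244 on the plus strand, with a log2 fold of 9.78 ± 0.89 (SD, n = 4). It was followed by the HIST3 locus on chromosome 1 at 228646199 to 228646254 (plus strand), with 8.97 ± 0.65 (SD, n = 4). Chromosome 6 at 26158484 to 26158832 (plus strand) had 7.94 ± 0.34 (SD, n = 4), and 26217605 to 26217662 (plus strand) had 7.86 ± 0.28 (SD, n = 4). The HIST2 locus on chromosome 1 at 149857737 to 149857855 (minus strand) had 8.93 ± 1.04 (SD, n = 4). The spread between libraries was widest on chromosome 6 at 26157255 to 26157341 (plus strand), with 9.09 ± 1.77 (SD, n = 4), and at 27806746 to 27806886 (plus strand), with 9.65 ± 1.70 (SD, n = 4). The locus at 27860501 to 27860920 on the minus strand held 10 regions and had 7.66 ± 0.35 (SD, n = 4). As for every locus named, the value is from the highest enriched peak touching its top region in each library. Here that region was 1 nt, at 27860518. The other 7, all on chromosome 6, started at 27861536, 26055983, 27114142, 26021078, 26188955, 27101132 and 27778193, with mean log2 folds of 7.96 to 9.16. RBFOX2 replicates 1 and 2 had peaks at 11 and 12 of the 15 loci and IgG at 8, and 0 of these were enriched.

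Outside the windows 2 loci were enriched in all 4 SLBP libraries, both named after their values were seen. On chromosome 11 at 118965605 to 118966108 (minus strand) the log2 fold was 8.60 ± 1.14 (SD, n = 4), and the highest IgG peak there had 1.50. On chromosome 6 at 31958261 to 31958279 (plus strand) the log2 fold was 5.29 ± 1.03 (SD, n = 4), and the IgG list held an enriched peak there at 4.77.

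SLBP libraries shared most of their enriched peaks with each other. Over the 12 ordered pairs of libraries a mean of 82.6% of enriched peaks overlapped an enriched peak of the other library (range 71.5% to 93.2%). The odds ratio against non-enriched peaks was at least 7378 in every pair, with a largest Fisher's exact p of 1.22e-289. The mean was 87.3% between libraries of the same RNase I amount and 80.2% between amounts (range 71.5% to 87.6%). Both values for replicates 3 and 4, at the lower amount, lay above that range (91.7% and 93.2%). For replicates 1 and 2, at the higher amount, 74.3% lay inside it and 90.1% above it. The difference was not tested, and replicate number changes together with RNase I amount.

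RBFOX2 and SLBP shared few enriched sites. The RBFOX2 libraries had 25.8 times as many enriched peaks on average, 6717 against 260.5 (exact permutation p = 0.133, two-sided, n = 2 and 4, the smallest p possible). That ratio depended on the limits: stricter ones gave 2975.5 against 227, and merging touching peaks gave 35.2 times as many sites. On the fold limit alone, 8974 and 11300 RBFOX2 peaks passed, against 1660, 1366, 350 and 1545 SLBP peaks. A mean of 1.11% of the enriched SLBP peaks overlapped an enriched RBFOX2 peak, 2 to 4 peaks in each pair of libraries, and 0.060% of the enriched RBFOX2 peaks overlapped an enriched SLBP peak. Among peaks touching any peak of the other antibody, enriched ones were set against the rest for lying on enriched peaks. Of RBFOX2 peaks in SLBP lists the odds ratios were 1.30 to 5.50 over 8 pairs, each resting on 3 to 6 peaks, with a smallest unadjusted Fisher's exact p of 0.00809. Of SLBP peaks in RBFOX2 lists they were 0.743 to 2.64, with a smallest Fisher's exact p of 0.117. Of the 2618 RBFOX2 and 90 SLBP regions, 1 was shared: chromosome 6 at 31958261 to 31958279, with lowest log2 folds of 3.87 in RBFOX2 and 4.51 in SLBP, where IgG was enriched as well. The number of shared regions ran from 0 to 3 over other settings. Enriched RBFOX2 peaks were wider, with a mean of the library medians of 53 nt against 27.5 nt (exact permutation p = 0.133, two-sided, n = 2 and 4). Part of this came from how peaks were split: with touching peaks merged the medians averaged 66.5 nt against 52.25 nt (exact permutation p = 0.133, two-sided, n = 2 and 4). Both RBFOX2 libraries had 40 U of RNase I, while the SLBP means pool 40 U and 5 U libraries. Merged SLBP medians averaged 47 nt at 40 U and 57.5 nt at 5 U.

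**Figure D3:**
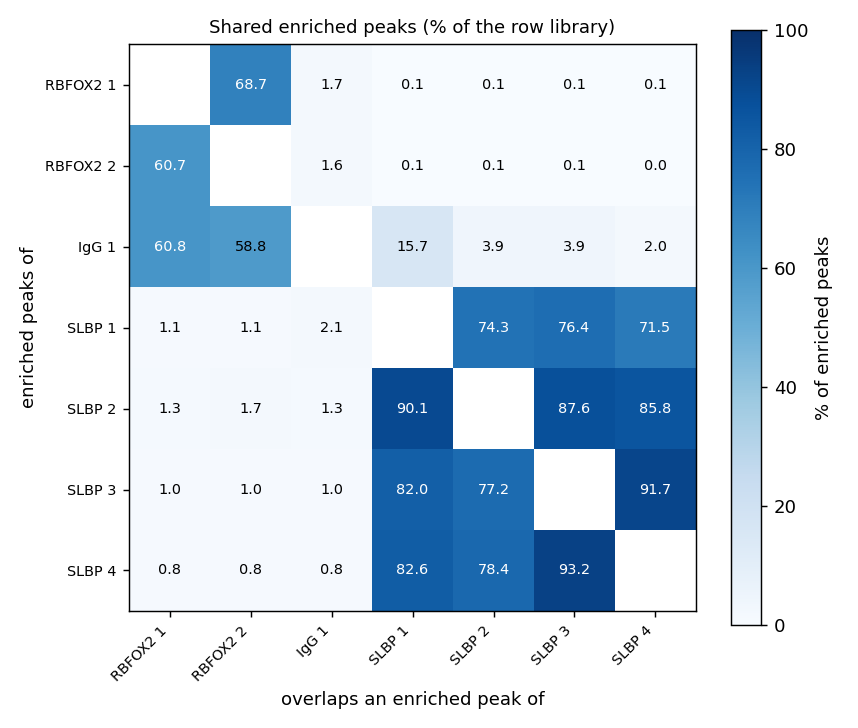
Percent of the enriched peaks of 1 library (row) that overlapped an enriched peak of another (column) by at least 1 nt on the same strand, for the 7 libraries. SLBP pairs lie between 71.5% and 93.2%, the RBFOX2 pair at 68.7% and 60.7%, and SLBP in RBFOX2 at 1.72% or less.

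The few enriched IgG peaks lay at enriched RBFOX2 peaks more often than other IgG peaks did. They also did so at enriched SLBP peaks, but at only 4 merged sites. Of the 51, 31 (60.8%) overlapped an enriched RBFOX2 peak, 30 of them in both replicates, against 621 (2.19%) of the 28310 other IgG peaks (odds ratio 69.1, Fisher's exact p = 4.01e-38). Enriched peaks of at least 1 SLBP library lay at 8, of both antibodies at 2 and of neither at 14. With touching peaks merged, 25 of 40 IgG sites (62.5%) lay at enriched RBFOX2 peaks and 4 at enriched SLBP peaks; 6 of the 8 peaks were pieces of 2 sites enriched in SLBP replicate 1 alone. Among IgG peaks that touched any peak of SLBP replicate 1, 33.3% of the enriched ones and 0.904% of the others lay on an enriched peak of it (odds ratio 54.8, Fisher's exact p = 5.19e-11). The same odds ratio was 17.6, 21.8 and 7.98 for SLBP replicates 2, 3 and 4 (Fisher's exact p = 0.00762, 0.00546 and 0.130). These rested on only 2, 2 and 1 enriched IgG peaks. The peaks came from the same 2 sites, on chromosomes 17 and 6, so the 3 values are not independent. For RBFOX2 replicates 1 and 2 the odds ratio was 32.8 and 29.7. The highest enriched IgG peak, on chromosome 17 at 18965405 to 18965452 (plus strand), had a log2 fold of 8.29 in IgG. It had 6.31 and 3.52 in RBFOX2 and 8.24, 7.35, 6.12 and 3.58 in SLBP, the last without passing the p-value limit. Next came chromosome 14 at 50329528 to 50329531 (minus strand, 6.40) and chromosome 17 at 39874406 to 39874445 (plus strand, 6.37), where the RBFOX2 lists were not enriched; the chromosome 14 peak was enriched in SLBP replicate 1, at 5.44. Chromosome 2 at 240287304 to 240287463 (minus strand) had 6.31 in IgG and 8.89 and 8.91 in RBFOX2, and lies in the first RBFOX2 locus named above. Chromosome 10 at 724430 to 724447 (minus strand) had 5.40 in IgG and 8.48 and 6.33 in RBFOX2. The test is within 1 IgG library. Of the 100 RBFOX2 regions with the highest fold, 61 were touched by an IgG peak of log2 fold of at least 1. Of the 100 with the lowest, 10 were (odds ratio 14.1, Fisher's exact p = 1.80e-14). That limit lies under the IgG list's median log2 fold of 1.31, and enriched IgG peaks touched 19 and 0 regions. Region width and input level were not held equal between the 2 sets.

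**Figure D4:**
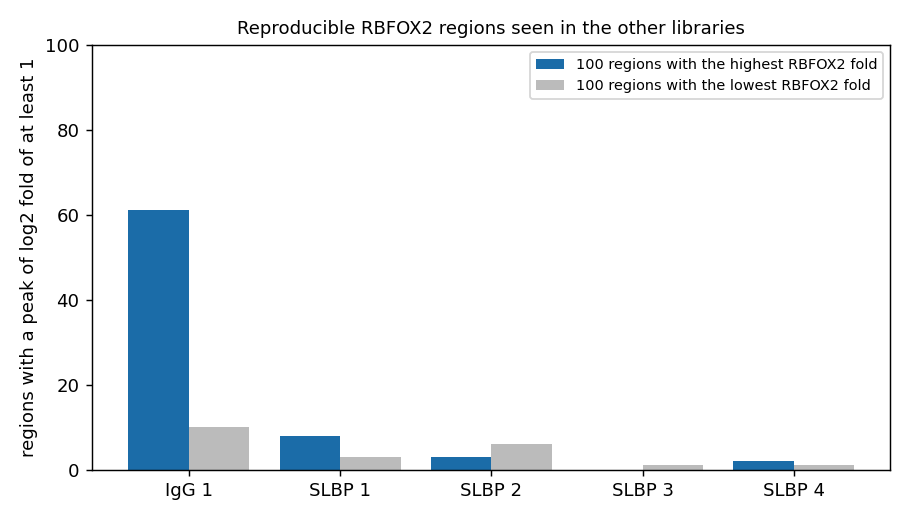
Number of reproducible RBFOX2 regions (vertical axis) touched by a peak of log2 fold of at least 1 in the IgG library and in each SLBP library (horizontal axis), for the 100 regions with the highest (blue) and the 100 with the lowest (grey) RBFOX2 fold. IgG had 61 against 10, and the 4 SLBP libraries 8 or fewer in either set. The median log2 fold of all peaks was 1.31 in IgG and 1.57, 1.46, 0.66 and 1.17 in SLBP replicates 1 to 4. The same limit is therefore not equally strict in each list.

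SLBP libraries made with 40 U and with 5 U of RNase I had similar numbers of enriched peaks, and a larger share of these lay in the histone windows in both 5 U libraries than in either 40 U library. Enriched peaks averaged 258.5 ± 36.1 (SD, n = 2) at 40 U and 262.5 ± 37.5 (SD, n = 2) at 5 U (exact permutation p = 0.667, two-sided). The histone share was 84.2% ± 3.0 (SD, n = 2) at 40 U and 93.2% ± 1.2 (SD, n = 2) at 5 U; the groups did not overlap, and the exact permutation p was 0.333, the smallest possible. Outside the windows 51 and 32 enriched peaks were found at 40 U and 17 and 18 at 5 U. All peaks averaged 20691.5 at 40 U and 13548 at 5 U (exact permutation p = 0.333, two-sided, n = 2 and 2). The median width of enriched peaks was 27 nt at 40 U and 28 nt at 5 U on average (exact permutation p = 1, two-sided, n = 2 and 2). With touching peaks merged into sites it was 47 nt at 40 U and 57.5 nt at 5 U, without overlap between the groups (exact permutation p = 0.333, two-sided, n = 2 and 2, the smallest possible). Replicate number and RNase I amount change together here, so they cannot be told apart. With looser limits on p or fold the difference of 40 U minus 5 U was −23.5 and −21.8 percentage points in histone share and 57.5 and 51.5 enriched peaks, and with stricter limits the share differed by −4.07 points, against −9.09 as reported.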

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

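The test of the 100 highest against the 100 lowest RBFOX2 regions was chosen before its result was seen, and the other tests of explanations given here, those on SLBP signal and on any antibody in IgG, on SLBP loci outside the windows and on IgG peaks in the windows, were chosen after related values had been seen.

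In 3 of 17 measures compared across the 4 SLBP libraries, 1 library lay far from the others, judged by its gap relative to the range. Merged into sites, the enriched peaks of SLBP replicate 1 made 160 sites, against 112, 116 and 116. In SLBP replicate 3, 82.6% of the peaks with a log2 fold of at least 3 also passed the p-value limit, against 17.1%, 17.1% and 15.3%. That library had 350 peaks past the fold limit, against 1660, 1366 and 1545, while the numbers passing both limits were similar (289 against 284, 233 and 236). In SLBP replicate 4, 92.0% of the peaks in the histone windows were enriched (218 of 237), against 87.6%, 87.4% and 87.5%. That flag rests on how close the other shares lay to each other, and counting error was not weighed. Chance marks about 1 in 20 such groups, and the measures overlap.

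Enriched IgG peaks lay at RBFOX2 sites (25 of 40 merged sites), and 4 of the merged sites lay at SLBP peaks. RBFOX2 signal in the IgG library is a candidate explanation. Of the 100 highest RBFOX2 regions, 61 were touched by an IgG peak of log2 fold of at least 1, against 10 of the 100 lowest (odds ratio 14.1, Fisher's exact p = 1.80e-14). The SLBP libraries gave 8 against 3, 3 against 6, 0 against 1 and 2 against 1. The limit of 1 lies under the IgG list's median log2 fold of 1.31, and enriched IgG peaks touched 19 against 0 regions. Region width was not held equal between the 2 sets, and wider regions are easier to touch. Input level enters every fold and was not held equal either, so the test cannot single out RBFOX2 signal. Sites recovered with any antibody stay open: 23 of the 31 IgG peaks at RBFOX2 sites touched no peak of any SLBP list, which at unknown depth excludes nothing, and of the other 8, 25% (2 of 8, exact 95% interval 3.19 to 65.1) were enriched in an SLBP library. SLBP signal in the IgG library is argued against at the histone regions, with a median log2 fold of 0.41 (interquartile half-range 0.49) over 28 IgG peaks at SLBP histone regions. Mixed barcodes, carry-over between samples and RBFOX2 complexes held by the IgG beads stay open too, and no biological explanation was tested.

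RBFOX2 peaks in the histone windows lay below input in 68.8% and 78.7% of cases, against 32.5% and 30.9% elsewhere (odds ratios 4.56 and 8.27, Fisher's exact p = 2.30e-24 and 3.26e-50). In IgG the same measure was 20.5% in the windows and 10.7% elsewhere (odds ratio 2.15, Fisher's exact p = 0.00728). Low signal of any antibody at these RNAs stays open: in the windows 75.9% of the 83 IgG peaks (exact 95% interval 65.3 to 84.6) lay under the median of their own list outside them, against 81.3% and 88.3% in RBFOX2. The median log2 fold in the windows minus that outside was −0.74 in IgG and −1.30 and −1.96 in RBFOX2, and with 1 IgG library these differences cannot be tested. Mitochondrial peaks lay below input in 86.3% and 97.9% of cases in RBFOX2, 66.2% in IgG and 46.4%, 60.2%, 77.5% and 81.4% in SLBP replicates 1 to 4. No biological explanation was tested.

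SLBP was enriched in all 4 libraries at 2 loci outside the histone windows. Background shared with IgG could account for the locus on chromosome 6, as 1 of the 2 loci held an enriched IgG peak, and the chromosome 11 locus did not. Windows drawn too narrow by up to 1 Mb account for neither locus, as 0 of the 2 lay within 1 Mb of a window. No window lies on chromosome 11, so this distance cannot show whether the windows leave out a histone gene there. Shared background cannot be decided for the set with 2 loci, and binding to an RNA outside the clusters stays open, as untested. Loci were not matched to genes, so whether the chromosome 11 locus lies in a histone gene is unknown. Every histone share given here counts its peaks as outside.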

How the results depend on the processing

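Merging touching peaks (for counts, widths and IgG), leaving out peaks at enriched IgG peaks and the thresholds applied to IgG were tests chosen after the data were seen. Of 88 alternative values, 18 moved beyond tolerance: 1.5 times for counts, 1 SD between replicates for differences, and the side of the threshold for tests. The other 70 include differences that changed sign within that SD. The cause was not tested except where stated. The SLBP histone share stayed between 73.2% and 92.1%, the RBFOX2 overlap between 61.2% and 67.2% and the SLBP overlap between 74.4% and 84.1%. Stricter limits gave 2975.5 enriched RBFOX2 peaks on average and 939 RBFOX2 regions, as fewer peaks can pass. Merging gave 4438.5 RBFOX2 and 126 SLBP sites by construction. IgG had 135, 168 and 15 enriched peaks with the looser p, the looser fold and the stricter limits. In that order the difference of 40 U minus 5 U in histone share was −23.5, −21.8 and −4.07 percentage points. The difference in enriched peaks was 57.5 with the looser p and 51.5 with the looser fold, and that in median width 3.25 nt with the looser p and −10.5 nt with touching peaks merged. Regions of both antibodies numbered 2 with the looser p, 3 with the looser fold, 0 with stricter limits and 2 with regions from at least 2 libraries. Leaving out each library in turn gave 5954 to 7480 enriched RBFOX2 peaks, 251 to 269.7 SLBP peaks and a histone share of 86.9% to 90.9%. For 40 U minus 5 U it gave −30.5 to 22.5 enriched peaks, with the sign turned to 21.5 without replicate 2 and 22.5 without replicate 3. It gave −4 to 2 nt in width, the 2 without replicate 4, and −11.2 to −6.98 percentage points in histone share.

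With the replicate block, pairing RBFOX2 and SLBP 40 U by replicate number, the histone shares differed by 84.1 percentage points, the same as without pairing; the exact permutation p was 0.5 paired and 0.333 unpaired, each the smallest possible, so pairing could change no call. Analyses of the motif, hexamers, gene parts, stem-loop, gene lists and annotated histone genes, with their alternatives, were not run. Depth is unknown, which limits how firmly weak peaks can be compared between libraries.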

Other observations

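The counts outside the windows and on mitochondrial RNA described here, and the exact permutation tests on them, were chosen after the data were seen.

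Enriched SLBP peaks outside the histone windows gathered at a single locus in part. The chromosome 11 locus at 118965605 to 118966108 held 15, 13, 10 and 11 of the 51, 32, 17 and 18 such peaks of replicates 1 to 4, leaving 36, 19, 7 and 7 elsewhere. Enriched IgG peaks were touched by 6, 3, 3 and 2 of them. As a share of all peaks outside the windows, the enriched ones made up 0.224%, 0.177%, 0.102% and 0.182%. Enriched peaks outside the windows averaged 41.5 at 40 U and 17.5 at 5 U (exact permutation p = 0.333, two-sided, n = 2 and 2, the smallest possible).

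Mitochondrial RNA gave 138, 113, 138 and 113 peaks in SLBP replicates 1 to 4, with 0, 1, 0 and 0 of them enriched. Their median log2 folds were 0.06, −0.31, −0.37 and −0.45. Their mean was −0.27, against −1.24 in the RBFOX2 libraries (exact permutation p = 0.133, two-sided, n = 4 and 2, the smallest possible). In IgG 2 of 157 were enriched.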
